A study of Felis catus with 3 samples.

How the data were processed

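The series holds 3 droplet single-cell RNA libraries from the epidermis of domestic cat fetuses at fetal stage 20, which the labels place at 44 to 48 days after conception. Per the labels' protocols, dorsal skin was digested with dispase, the epidermis was scraped off and dissociated, and cells that bound an antibody against c-KIT, the receptor kinase of melanoblasts, were captured on magnetic beads. Libraries were 3' tagged with unique molecular identifiers (UMIs) on the 10x Genomics platform with a target of 6000 cells each. The groups follow the genotype labels, with 1 library per group: a nonorange male with the ancestral allele of Arhgap36, an orange male with the derived allele, and a heterozygous female with both.

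The deposited values are whole-number UMI counts per gene and cell, made with Cell Ranger 7.1.0, per the submitters' processing notes. Both males share 1 table that had been aggregated before deposit, and barcodes were assigned to them by suffix, through the order of the libraries in an aggregation sheet deposited with it. The female has a table of its own. Whether the aggregation equalised the depth of the males, and the genome build of both tables, are not given in the sources used here, so no coordinates are printed. Male barcodes did not look like those of the chemistry named in the labels, which is a further limit on levels set between the female and the males. Both tables list the same 35688 genes, of which 34995 were matched by symbol or locus tag to a RefSeq table of the domestic cat (assembly F.catus_Fca126_mat1.0), used only for gene names, chromosomes and neighbours. All columns of per-cell values belong to these 3 libraries.

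Total counts as deposited were 86164975 in the nonorange male (4376 cells), 71004146 in the orange male (3904 cells) and 103840023 in the female (6340 cells). Cells with fewer than 500 genes (842, 1119 and 391 in that order) or over 20% mitochondrial UMIs (68, 128 and 42 of the rest) were removed, with 37 mitochondrial genes in the gene list. Doublets were called in each library with the Scrublet method of scanpy 1.11.5 and removed: 54, 32 and 127 cells. This left 3412, 2625 and 5780 cells, with medians of 19393, 20088 and 8824 UMIs per cell. Log-transformed counts per 10000 of 2000 variable genes were reduced to 30 principal components, linked to 15 neighbours and clustered with the Leiden method at resolution 1.0 (igraph 0.11.9), with all libraries together and no integration. ARHGAP36 and the genes of the lists on pigment, PKA, CREB, hedgehog and X neighbours (102 genes once all were counted) were kept out of the variable genes, so that these genes did not set the classes. Other genes named in the text were not kept out.

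The 24 clusters were named from marker lists of melanocytes, Schwann cells, keratinocyte layers, hair follicle, sebaceous gland, fibroblasts, dermal papilla, vessels, immune cells, mast cells, Merkel cells, erythroid cells and muscle. A name needed a mean log2 fold of at least 1.0 over the detected markers, at least 3 markers up 2-fold, and at least 1 of its markers, and no more of another list, among the 10 leading genes. The fold that ranks the leading genes was taken against cells outside the same candidate class. That choice was made after the data were seen, because the fold against all other cells put no melanocyte marker among the leading genes of clusters rich in ARHGAP36. Clusters that resembled basal keratinocytes failed the rule, so the planned control of basal keratinocyte-like cells was replaced by clusters taken by number: cluster 2 in the males and cluster 0 in the female.

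UMIs were summed per library over the melanocyte-like cells and divided by all UMIs of those cells to give counts per 1000000 UMIs (CPM). Ratios carry exact conditional binomial (Clopper-Pearson) intervals, sums exact Poisson intervals and shares exact binomial intervals, all at 95%. With 1 library per group no test, p-value or standard error was made. Counts of genes or list members are of ratios beyond a stated fold (1.5 or 2), not of genes that passed a test, and all intervals cover counting error only. A sum of 0 was set to a floor of 3 counts over the library's cells, which gives a bound. Bounds from this floor are tighter than the ends of the exact intervals. For shares of cells with a UMI, each cell was thinned to 4000 UMIs by random draws without replacement and shallower cells were left out. In the female and, as a control, the orange male, thinned melanocyte-like cells with at least 1 ARHGAP36 UMI were compared with those with none.

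The choices of groups, cell filter, lists, alternatives and the rule for named genes were made before the data were examined. Genes were named if they had at least 50 CPM in melanocyte-like cells of either male, at least 20 summed UMIs, a symbol, and a level, in the library where they were higher, no lower than in the other cells of that library. The 12 with the highest and the 12 with the lowest ratio were taken, ranked with 1 UMI added, and 5 and 5 for the keratinocyte cluster. Members of the lists with the most UMIs or the largest ratios are named besides, and further members and TOP2A were chosen after their values were seen. Of 3554 genes with a symbol at that level, 2569 were eligible, and 985 were below the other cells and are not named. Lists covered pigment synthesis and melanosomes, melanocyte regulators, pheomelanin and redox genes, protein kinase A (PKA) signalling, CREB-responsive genes, the hedgehog pathway, X-chromosome neighbours of ARHGAP36, S and G2/M phase, dissociation stress, lysosome, MAPK output, neural crest progenitors, cholesterol synthesis, other RhoGAP genes, keratin, collagen, globin, mast cell and Schwann cell genes of other cells, and housekeeping genes. List medians used members with at least 20 summed UMIs, with an order-statistic interval over members and the percentile among 10000 random lists of the same size matched on expression. The percentile describes these libraries and is no test. Values of some single list members are not reported here. The first pattern weighed in the closing section had been written down as lower pigment genes as a group, which the list's median did not bear out, and was rewritten for the lower members.

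Ratios and list percentiles were tested on simulated data for the comparison of the males' melanocyte-like cells. Of 14358 genes simulated, 200 were changed. Genes changed by a log2 of 1.0 came out at a median of 1.01, those changed by 2.0 at 1.98, those changed by -1.0 at -0.97 and those changed by -2.0 at -2.01. Intervals held the true value for 92.0% to 96.0% of the genes in each group. A list of 20 genes raised 2-fold lay at percentile 100.0 and a list of 20 unchanged genes at 34.2. Sums were drawn as Poisson counts, the model that the intervals assume, with no variation between cells or animals. The simulation therefore checks the computation only. Alternatives were another cell filter or none, doublets left in, other clusterings, marker gates in place of clusters, TMM scaling (edgeR 4.0.16) and size factors (DESeq2 1.42.0) in R 4.3.3, totals without mitochondrial, ribosomal and globin genes, subtraction of the profile of all cells, thinning, per-cell means, other count minimums and list means. The gate without a rule on mast and Schwann markers and the comparison of clusters by number were chosen after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.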

Results

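The 3 libraries held c-KIT-enriched epidermal cells of a nonorange male, an orange male and a heterozygous female cat fetus, with 1 library per group, so differences between libraries have no replicate check. After filtering, 3412, 2625 and 5780 cells remained, in that order. The kept cells of the female were shallower, with a median of 8824 UMIs per cell against 19393 in the nonorange and 20088 in the orange male. The female's table was also processed apart from that of the males, which limits levels set across the tables.

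Melanocyte-like cells, whose clusters all had the melanosome genes PMEL and MLANA among their leading genes, made up 24.2% (22.8 to 25.7) of the kept cells of the nonorange male (827 cells), 22.3% (20.7 to 24.0) of the orange male (586 cells) and 38.7% (37.4 to 39.9) of the female (2234 cells). The antibody enrichment, the cell filter and the depth of each library can set these shares. A planned gate on single-cell markers, which asks for 3 of 8 melanocyte markers and drops any cell with a mast or Schwann cell marker, FABP7 and S100B among them, kept 7.83%, 1.41% and 14.4% in the same order. KIT itself, the target of the enrichment, stood at 357 CPM in melanocyte-like cells of the nonorange male, 416 CPM in the orange male and 322 CPM in the female. Hair follicle-like cells with TCHH, KRT25 and KRT71 formed 2.84%, 2.67% and 2.54% of the cells in the same order. Suprabasal keratinocyte-like cells with LORICRIN formed 2.29%, 2.86% and 5.09%, and fibroblast-like cells with COL1A1 and COL3A1 0.703%, 0.648% and 1.85%. Macrophage-like cells with CD74 and TYROBP numbered 3, 3 and 13. The remaining 69.8%, 71.4% and 51.6% lay in clusters without a name, among them clusters with CXCL14 and BCAM and a cluster with KRT2 and GJA1 among the leading genes. Different clusters held most melanocyte-like cells in each library. Genes of the pigment, PKA, CREB, hedgehog and X-neighbour lists took no part in the clustering, whereas other named genes such as FABP7 and CNTNAP2 were not kept out. Cluster 21 held 723 of the 827 cells of the nonorange male, cluster 20 held 406 of the 586 of the orange male, and clusters 12 and 4 held 1097 and 838 of those of the female. Cluster 13 held melanocyte-like cells of all libraries (83, 37 and 265).

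ARHGAP36, the X-linked gene whose allele defines the groups, was detected in melanocyte-like cells of the orange male and the female and in none of the nonorange male. Its 1878 UMIs in the orange male gave 207 CPM (198 to 217) and its 1547 UMIs in the female 86.7 CPM (82.4 to 91.1). The nonorange male had 0 UMIs among 14217153, which allows up to 0.211 CPM. Against the floor, the level was at least 981-fold higher in the orange than in the nonorange male, a log2 ratio of at least 9.94. It was at least 411-fold higher in the female than in the nonorange male. The exact interval of the males' ratio reached down to 797-fold, a log2 ratio of 9.64. ARHGAP36 in the female stood at a log2 ratio of -1.26 (-1.35 to -1.16) to the orange male. The labels call the derived allele a deletion but do not say which part of the gene it removes, so these 3' tags do not check the genotype.

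Of the melanocyte-like cells, 471 of 586 in the orange male (80.4%, 76.9 to 83.5) and 647 of 2234 in the female (29.0%, 27.1 to 30.9) held an ARHGAP36 UMI. In the nonorange male it was 0 of 827, which allows up to 0.363% of cells with a UMI at the floor and 0.445% by the exact interval. Thinned to 4000 UMIs per cell, the shares were 52.0% (47.7 to 56.2) in the orange male, with 32 cells left out, and 22.5% (20.6 to 24.5) in the female, with 444 left out. With 2 UMIs required they were 23.8% and 9.50%. Under the gate on single-cell markers the thinned shares were 3.45% (0.0873 to 17.8) of 29 cells in the orange male and 7.04% (5.18 to 9.31) of 639 cells in the female, and the log2 ratio of ARHGAP36 between the males was at least 4.86. The thinned nonorange male stayed at 0 of 822 cells, with 5 left out. In all other kept cells the share was 0.883% in the orange male and 1.18% in the female, or 0.0997% and 0.373% thinned with 32 and 331 cells left out. Those cells were deeper, with medians of 22225 and 11278 UMIs against 14099 and 6646 in the melanocyte-like cells. The level in other cells was 0.352 CPM (20 UMIs) in the orange male and 0.653 CPM (54 UMIs) in the female.

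**Figure D1:**
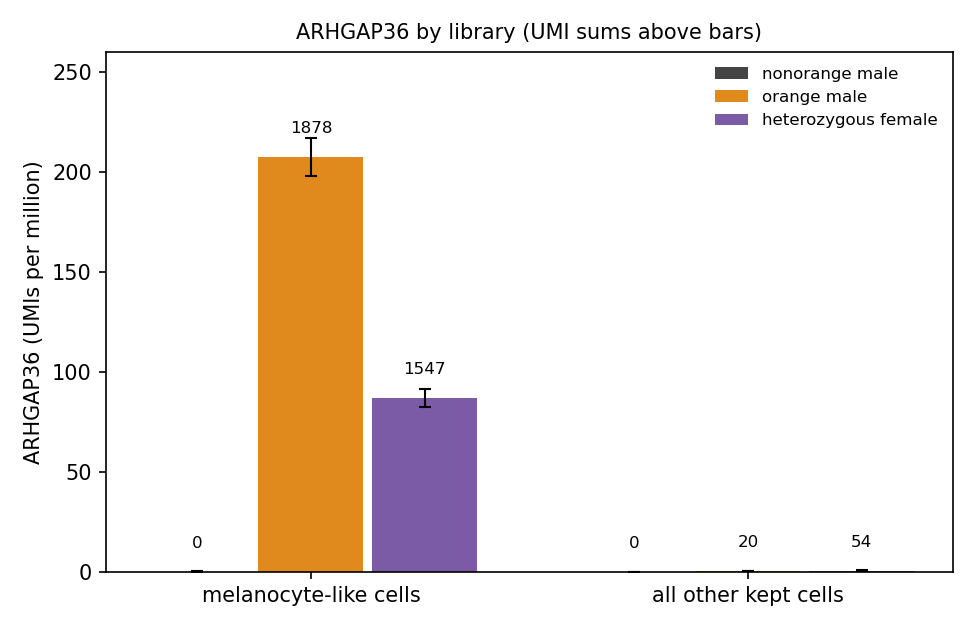
Bars give ARHGAP36 in CPM (vertical axis) in melanocyte-like cells and in all other kept cells of each library, with exact 95% Poisson intervals that cover counting error only and the UMI sum above each bar. ARHGAP36 reached 207 CPM in melanocyte-like cells of the orange male and 86.7 CPM in the female, against 0 UMIs in the nonorange male and under 1 CPM in other cells.

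Within the female, ARHGAP36 differed between the clusters of melanocyte-like cells. Cluster 4 held 237 CPM (224 to 250), close to the 247 CPM (234 to 260) of cluster 20 of the orange male, and cluster 12 held 17.2 CPM (14.5 to 20.2). An ARHGAP36 UMI was found in 61.5% of the cells of cluster 4 and 6.93% of those of cluster 12, at medians of 5341 and 6966 UMIs per cell, and in 54.7% and 4.49% after thinning, with 227 and 183 cells left out. The 108 cells of the orange male in cluster 21 held 123 CPM (108 to 140).

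Between the males, the question was which genes of melanocyte-like cells differ with the orange allele. The genes highest in the orange male after ARHGAP36 included LUM and DCN, which encode matrix proteoglycans, the phosphodiesterase gene PDE11A, the peptide hormone gene CCK and the brain-type fatty acid binding protein gene FABP7. LUM had 1 UMI in the nonorange and 612 in the orange male, a log2 ratio of 9.91 (7.42 to 15.21). DCN stood at 1.62 and 157 CPM (log2 ratio 6.60, 6.01 to 7.27), PDE11A at 1.41 and 91.9 CPM (6.03, 5.39 to 6.75) and CCK at 1.62 and 97.4 CPM (5.91, 5.32 to 6.58). FABP7 stood at 30.3 CPM in the nonorange and 501 CPM in the orange male, a 16.5-fold difference. SERPINF1, CNTNAP2, ABCA9, TMEM163, ASIP and DAB1 completed the higher genes, with log2 ratios from 3.93 down to 2.94. ASIP, which encodes the agouti signalling protein, an antagonist of the melanocortin receptor, stood at 7.81 and 69.0 CPM (log2 ratio 3.14, 2.85 to 3.45). DCN was also abundant in the other cells of both males, at 129 and 119 CPM.

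The genes lowest in the orange male included DCT, which encodes dopachrome tautomerase of eumelanin synthesis, and 3 genes of cyclic nucleotide phosphodiesterases. DCT stood at 204 CPM in the nonorange and 26.7 CPM in the orange male, 7.63-fold lower (log2 ratio -2.93, -3.13 to -2.74). PDE3A had a log2 ratio of -2.77 (-3.04 to -2.50), PDE4B of -2.41 (-2.61 to -2.22) and PDE4D of -2.13 (-2.22 to -2.03). PKIB, which encodes an inhibitor of PKA, stood at 613 and 171 CPM (-1.84, -1.92 to -1.76). FXYD6 had the lowest ratio, -3.14 (-3.49 to -2.80), and FGF13, NCKAP5, FSTL4, PHYHIP, CNIH3 and MRPL51 lay between -2.81 and -1.72. MRPL51 was also lower in the keratinocyte cluster, at -1.75, whereas PDE4D had -0.14 there. The gate on single-cell markers turned FXYD6 to 0.35 and NCKAP5 to 1.27, with LUM at 0.16, CNTNAP2 at 0.40 and PDE4D at -0.07. Without the rule on mast and Schwann markers, a gate chosen after seeing the data, LUM was at 6.12, DCN at 2.47, CNTNAP2 at 3.52 and PDE4D at -0.60.

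Pigment and melanosome genes went both ways. Of 27 measured members, 6 were at least 1.5-fold lower and 4 at least 1.5-fold higher in the orange male, with a median log2 ratio of 0.22 (-0.20 to 0.37). TYRP1, an enzyme of eumelanin synthesis, stood at 3872 CPM in the nonorange and 1438 CPM in the orange male (-1.43, -1.46 to -1.40). The other lower members were DCT, SYTL2 (-1.09), SLC24A5 (-0.74), SLC24A4 (-0.64) and OCA2 (-0.63). TYR, the rate-limiting enzyme of melanin synthesis, had a ratio of -0.24 (-0.29 to -0.18), PMEL of 0.22 (0.20 to 0.24) and MLANA of 0.34 (0.30 to 0.38). LYST, a regulator of lysosome-related organelles, was highest at 1.34 (1.29 to 1.39), followed by RAB38 at 0.98, HPS5 at 0.70 and RAB27A at 0.63. The median lay at percentile 99.95 of matched random lists, while the mean of the members was -0.029. Under the gate on single-cell markers the median was -1.98.

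Melanocyte regulators had 3 of 17 members at least 1.5-fold higher and none lower, with a median of 0.18 (-0.03 to 0.57). TBX2 was highest at 2.33 (1.90 to 2.79), and MITF, the master regulator of the lineage, had 0.21. Of 12 genes linked to pheomelanin or redox balance, 3 were higher and none lower (median 0.12, 0.01 to 0.59). MFSD12, which acts in cysteine import into melanosomes, was highest at 1.43 (1.24 to 1.62), and the cystine transporter gene SLC7A11 had 14 and 9 UMIs in the nonorange and orange male. Under the gate on single-cell markers the medians turned to -0.97 for regulators and -0.38 for pheomelanin genes.

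Of 24 measured genes of the PKA pathway, 7 were at least 1.5-fold lower and 3 higher in the orange male, with a median of -0.015 (-1.61 to 0.39). The lower members were PDE3A, PDE4B, PDE4D, PKIB, PDE3B (-2.40), ADCY7 (-2.72, -5.07 to -1.04, on 3 and 31 UMIs) and RAPGEF3 (-1.61). The higher were ADCY3 (1.45), PKIG (0.93) and PRKACB, a catalytic subunit of the kinase, at 0.72 (0.61 to 0.82). PRKACA, another catalytic subunit gene, had 23.0 CPM in the orange and 20.1 CPM in the nonorange male (0.20, -0.07 to 0.46). Of 18 CREB-responsive genes, 9 were lower and 2 higher, with a median of -0.56 (-0.97 to 0.07), below all matched random lists (percentile 0.00). Of these, PDE4B and PDE4D also belong to the PKA list, and FOS (-0.81), FOSB (-0.97) and ATF3 (-0.59) to the list of dissociation stress. That list was itself lower, with 3 of 14 members lower, none higher and a median of -0.34 (-0.59 to -0.07). In the keratinocyte cluster the CREB list had a median of -0.26 with 1 of 17 members lower, itself at percentile 0.10 of matched random lists, the PKA list -0.19 with 6 of 19 lower and the stress list -0.04. Under the gate on single-cell markers the medians were -0.029 for CREB, -0.32 for PKA and 1.17 for stress genes.

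Among other groups, hedgehog genes had 4 of 9 members higher and none lower (median 0.26), among them GLI3 (1.29), CDON (0.97) and PTCH1 (0.79). G2/M genes had a median of -0.18 (-0.42 to -0.11) with CCNB2 (-0.59) as the 1 member lower by 1.5-fold, and S phase genes 0.10 with none of 13 beyond 1.5-fold. With clusters made in each library alone these medians were -2.89 and -0.45. Lysosome genes had a median of 0.20 with TFEB, a transcription factor of lysosomal genes, at 2.54. The 13 MAPK output genes had a median of 0.03, with SPRY4 at 2.03 and EPHA4 at -1.10. Neural crest progenitor genes had a median of 0.31 over 7 members, of which FABP7, SOX9 (1.48) and NES (0.77) were higher by 1.5-fold. Cholesterol synthesis (median -0.07), other RhoGAP genes (0.07) and housekeeping genes (-0.04) had medians near 0, with ARHGAP6 at 1.90. Under the gate on single-cell markers the medians were 0.49 for G2/M, -0.19 for lysosome, 0.63 for MAPK, -2.77 for neural crest and 0.38 for cholesterol genes, and a minimum of 100 summed UMIs brought the hedgehog median to -0.0094 over 6 members.

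Markers of other cell types were not level between the males in the melanocyte-like cells. Keratin genes had a median of -0.43 (-1.57 to -0.07), with KRT5 at -1.57. The median turned to 2.89 under the gate on single-cell markers, to 0.29 without its rule on mast and Schwann markers and to 0.0085 with thinning. Collagen and matrix genes had 0.49 over 5 members, among which LUM and DCN, at 67.5 and 157 CPM in the orange male, exceeded the 3.75 and 119 CPM of its other cells, while COL1A1 had 0.07 and COL1A2 -1.59, and the gate turned this median to -1.70. Schwann cell genes had -0.10 over 5 members, 0.50 with thinning and 1.39 with clusters made in each library alone, with S100B at 1.81. MBP had 6 UMIs in the orange and 109 in the nonorange male. No globin or mast cell gene of the lists reached 20 summed UMIs.

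In the keratinocyte cluster taken as a control (551 cells of the nonorange and 403 of the orange male), the SD of log2 ratios between the males was 0.259 over 3543 genes at 50 CPM, against 0.514 over 3679 such genes in melanocyte-like cells. The median absolute log2 ratio was 0.138 against 0.155. Cells of both males entered the keratinocyte cluster only where they clustered together. The melanocyte-like cells pooled several clusters, in most of which the males lay apart, so these spreads are not like for like. AFF3 was highest in the orange male there, at 4.11 (3.66 to 4.60), followed by ABI3BP (1.31), MCP-1 (1.25), VAV3 (1.14) and ADAM12 (1.10). ADGRB3 was lowest at -2.13 (-2.38 to -1.89), followed by HECW1 (-1.85), RFNG (-1.24), PEG3 (-1.22) and KHDRBS2 (-1.15).

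In female mammals most X-linked genes are expressed from a single X chromosome per cell, so the heterozygous female allows cells with and without ARHGAP36 transcripts to be compared inside 1 library. After thinning, 403 melanocyte-like cells held an ARHGAP36 UMI and 1387 did not. A cell without a UMI can still express the gene, as 266 of the 554 thinned cells of the orange male also lacked one. Cells with the UMI were lower in DCT (log2 ratio -2.45, -2.83 to -2.10), PDE3A (-2.39, -3.14 to -1.72), PDE4B (-2.15, -2.60 to -1.72), TYRP1 (-1.62, -1.72 to -1.52), PDE4D (-1.004, -1.16 to -0.86) and PKIB (-0.94, -1.12 to -0.77). They were higher in LUM (2.59, 1.66 to 3.58), TMEM163 (2.46, 2.07 to 2.86), PDE11A (2.36, 2.06 to 2.67), CNTNAP2 (2.04, 1.92 to 2.15), FABP7 (1.82, 1.67 to 1.97), CCK (1.78, 1.54 to 2.01) and ASIP (1.66, 1.38 to 1.94). Of the 23 named genes other than ARHGAP36, 22 had the sign of the males' comparison. The exception was SERPINF1, at -0.15 (-1.26 to 0.83), and CNIH3 had an interval that included 0 (-0.32, -1.75 to 0.90).

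**Figure D2:**
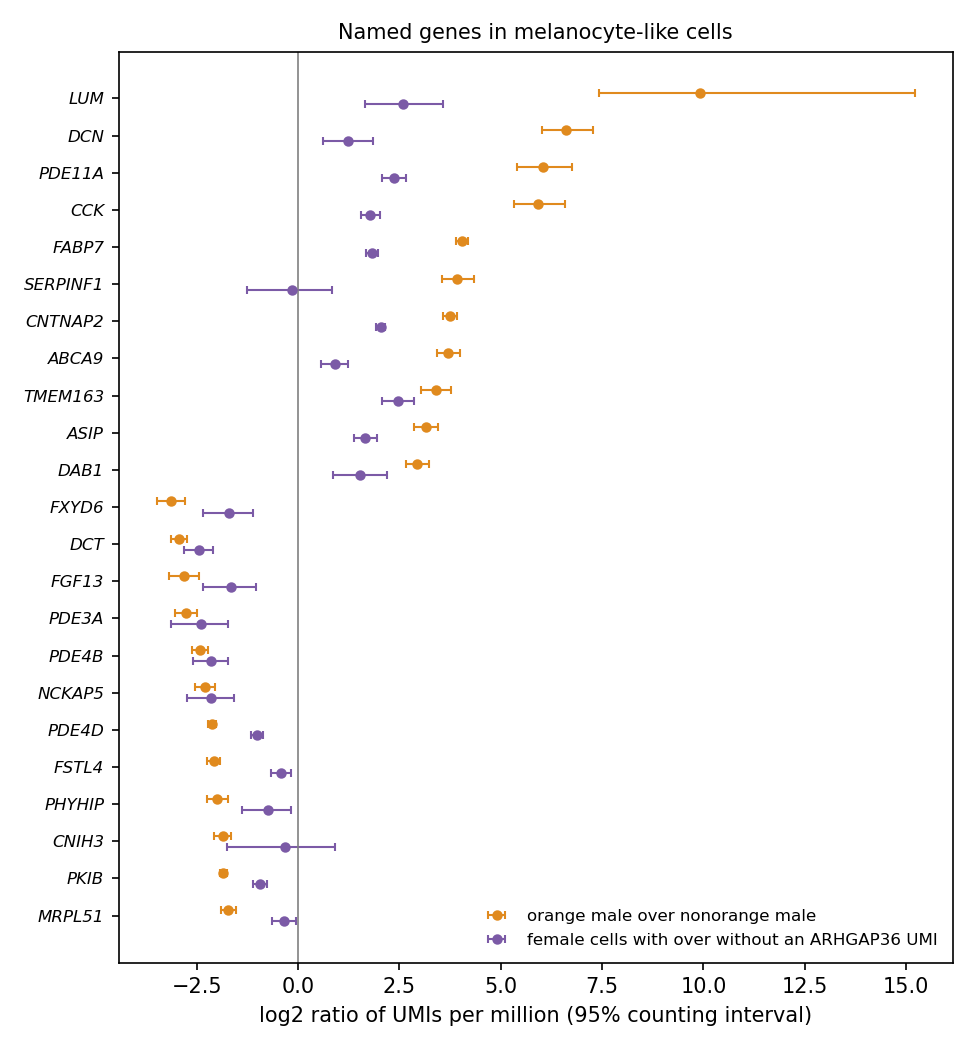
Points give the log2 ratio of CPM (horizontal axis) of the 23 named genes other than ARHGAP36 for the orange over the nonorange male and for female melanocyte-like cells with over those without an ARHGAP36 UMI, with 95% intervals that cover counting error only. The signs match in 22 of the 23 genes, with SERPINF1 at 3.93 and -0.15.

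In this split of the female, the pigment list had a median of 0.32 (-0.15 to 0.43), with 6 members higher and 5 lower, and the PKA list a median of 0.05 and a mean of -0.24 with 7 of 22 members lower, among them PDE3B (-1.56). The CREB list had -0.29 (-0.46 to 0.24), with PDE4B, SERPINE2 (-1.06) and PDE4D as its 3 lower members, and the stress list 0.07. The CREB median was 0.027 with 2 ARHGAP36 UMIs required and 0.25 between cluster 4 and cluster 12 of the female. LYST (1.16), SLC45A2 (1.12), GLI3 (1.46) and TBX2 (1.32) were higher in cells with the UMI. Genes of G2/M were lower in these cells, with 12 of 14 members and a median of -0.85 (-1.17 to -0.63). The same split in the orange male, where 288 cells had and 266 lacked a UMI, also gave a lower G2/M median, -1.17 (-1.87 to -0.50). The CREB list there had a median of -0.22 (-0.51 to 0.32), near that of the female, with 2 of 14 members lower and 2 higher. The pigment list had 0.17 (0.13 to 0.51), with 5 of 25 members higher and none lower, and the PKA list 0.17 with 1 of 20 lower and 2 higher. Although that male carries a single allele, NCKAP5 (-2.92, -5.31 to -1.18, on 3 and 21 UMIs), PDE4B (-1.07, -2.07 to -0.12), PDE4D (-0.50, -0.88 to -0.11) and TYRP1 (-0.36, -0.47 to -0.25) were also lower there, and CCK (0.94, 0.54 to 1.36), ASIP (0.69, 0.24 to 1.15), TMEM163 (0.58, 0.04 to 1.14), DCN (0.53, 0.27 to 0.80), CNTNAP2 (0.52, 0.31 to 0.73), FABP7 (0.47, 0.32 to 0.63) and PDE11A (0.42, 0.07 to 0.78) higher. DCT had 0.13 (-0.90 to 1.19) and PKIB 0.31 (-0.0011 to 0.62). Of the 23 named genes other than ARHGAP36, 18 had the sign of the males' comparison in that split, 10 of them with an interval that excluded 0, against 22 and 21 in the female.

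Across genes, which are not independent replicates, the ratio between the males and that of the female split had a Pearson correlation of 0.617 and a Spearman correlation of 0.437 over 2726 genes with at least 500 UMIs in both. Over the 532 genes that also had 500 UMIs in the split of the orange male, Pearson's r was 0.810 for the female split and 0.569 for that of the orange male. The Spearman correlations over these genes lay closer together, at 0.721 and 0.584. The female split shares no library with the males' comparison, whereas the split of the orange male does.

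**Figure D3:**
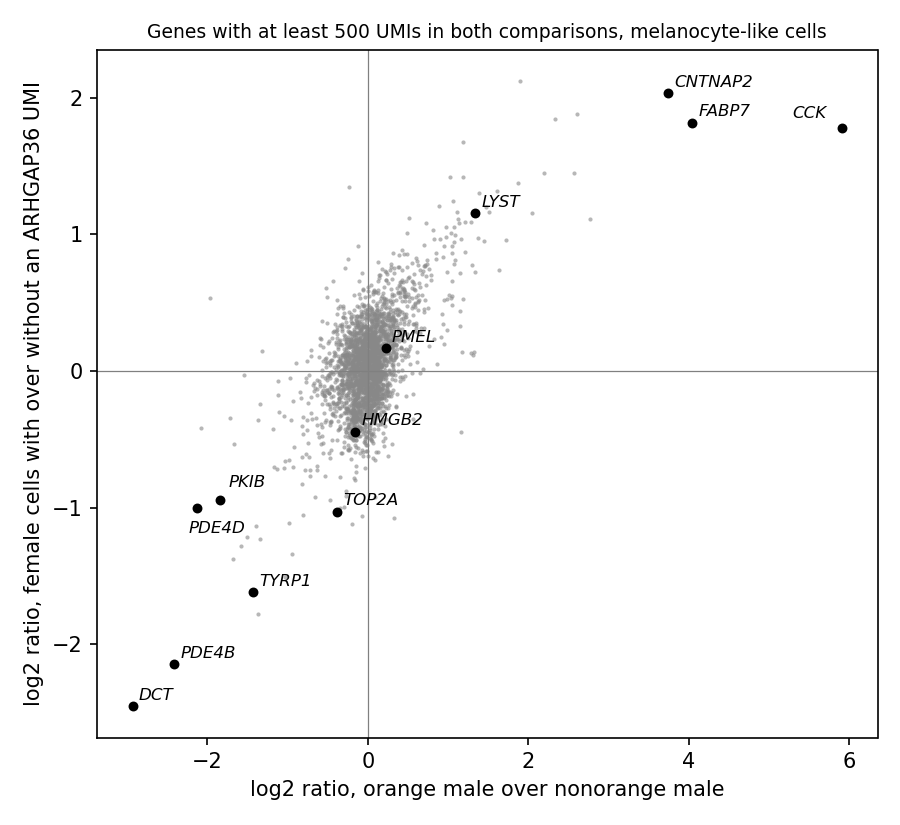
Each point is a gene with at least 500 UMIs in both comparisons (2726 genes), with the log2 ratio of the orange over the nonorange male on the horizontal axis and that of female melanocyte-like cells with over without an ARHGAP36 UMI on the vertical axis. DCT, PDE4B and TYRP1 lie low and CNTNAP2, FABP7 and CCK high on both, while the G2/M gene TOP2A is at -1.03 in the female split and -0.39 between the males.

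Set against the males, the female's melanocyte-like cells held DCT at 211 CPM, against 204 CPM in the nonorange and 26.7 CPM in the orange male, and PKIB at 367 CPM, between the males. CNTNAP2 stood at 299 CPM (322 CPM in the orange male) and TYRP1 at 1684 CPM, while PMEL at 2333 CPM was below both males. Of the pigment list, 5 members were at least 1.5-fold higher and 7 lower than in the nonorange male, and 1 higher and 3 lower than in the orange male. CREB-responsive genes had 9 of 18 members higher than in the orange male, and so did the stress list with 9 of 14. Other lists also differed between these libraries: 7 of 8 keratin genes (median 1.05) and 12 of 14 G2/M genes were higher in the female, and 7 of 17 lysosome genes lower. Of 810 genes at least 2-fold higher in the orange than in the nonorange male, the female's median position was 0.556 (0.522 to 0.610) on a scale from 0.0 at the nonorange to 1 at the orange male, and 65.1% lay between. For the 639 genes at least 2-fold lower it was 0.305 (0.243 to 0.361), with 57.6% between. The same quantity in the keratinocyte clusters was 0.489 and 0.338, with 48.5% and 50.8% between, and 0.446 and 0.231 over genes with at least 100 UMIs. Counts simulated from 1 common profile gave 0.446 and 0.382, with larger shares between, 79.4% and 81.7%. These positions compare tables that were processed separately. They were 0.0669 and 0.0305 under the gate on single-cell markers, and that of the lower genes was 0.177 with clusters made in each library alone, while other scalings gave 0.473 to 0.509 and 0.376 to 0.392.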

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

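Of the tests below, those on pigment genes, on genes of glial or dermal lineages and on 8 genes in the cells that cluster with the nonorange male were chosen only after the result was seen. Those on barcodes and on the share of these cells with an ARHGAP36 UMI were written down before that share was computed, when ARHGAP36 levels per cluster had been seen. ARHGAP36 also appeared in barcodes left out of the kept cells, at 7.63 CPM (5.42 to 10.4) in the orange male and 33.8 CPM (27.9 to 40.7) in the female. The nonorange male had 0 UMIs in 964 such barcodes. Such barcodes are those removed by the cell filter together with the called doublets, and these were not told apart. Doublets numbered 54 in the nonorange male, 32 in the orange male and 127 in the female.

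Of the pigment list, 6 members were at least 1.5-fold lower in melanocyte-like cells of the orange male, with a median log2 ratio of -0.92, whereas the pattern as first written down, a lower pigment list as a whole, did not hold. The median was -1.38 in thinned cells. Thinning leaves the expected share of each gene in a cell unchanged, so it could not decide on unequal depth. RNA of other cells was argued against only at the amount estimated from keratin and collagen UMIs. The median was -0.92 after the profile of all cells was subtracted at that amount. This took 1.65% and 1.89% of the UMIs of the nonorange and orange male and moved DCN from 6.60 to at least 9.52. So small an amount could change these members little, and larger amounts were not examined. Inside the female library, the 6 members had a median of -0.81 in cells with an ARHGAP36 UMI against cells without, 4 of them with intervals below 0. This argues against a difference between the males that is not linked to the allele as the whole cause for the set. OCA2 (-0.18, -0.36 to 0.0029) and SYTL2 (-0.12, -1.18 to 0.82) stay open. Other variants on the same X chromosome would part with the allele in this split and cannot be told apart from it. Splitting cells on a UMI gave a lower TYRP1 in the orange male too, -0.36 (-0.47 to -0.25), against -1.62 (-1.72 to -1.52) in the female. The members' median there was 0.091 with an SD of 0.30, over members that went both ways. As the whole cause the split was argued against for 3 of the 6 members, TYRP1, DCT and SLC24A5, whose intervals in the orange male lay above those in the female. DCT was already low in the orange male, on 19 and 16 UMIs. For OCA2, SLC24A4 and SYTL2 the intervals overlapped, so the split could not decide. An effect on this set of the allele, or of variants linked to it on the X chromosome, may be considered as a hypothesis. There was 1 library per group. The splits also part cells by ARHGAP36 level and cycle phase, as G2/M genes had medians of -0.85 in the female and -1.17 in the orange male. Cells with a UMI were also shallower before thinning. Their medians were 6851 UMIs per cell against 8072 without a UMI in the female, and 13176 against 16463 in the orange male.

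FABP7, LUM and some other genes known from glial or dermal cells were higher in melanocyte-like cells of the orange male, but the lists went both ways. Of 5 Schwann cell genes 2 were at least 1.5-fold higher and 2 lower, and of 5 collagen and matrix genes 2 were higher and 1 lower. Schwann cells or doublets with them were argued against at 4000 UMIs per cell, as PMEL was 1.001 times (0.961 to 1.04) as high in 341 cells with a FABP7 UMI as in 213 without, and MBP had 0 UMIs in the former. Fibroblast RNA as the source of LUM was argued against by LUM over COL1A1, which was 128 times that of fibroblast-like cells of the same library (612 and 98 UMIs against 202 and 4133). Expression of FABP7 and LUM in the melanocyte-like cells of this animal may be considered as a hypothesis. The source of the other genes, DCN and SERPINF1 among them, was not tested in these ways. In the female split LUM had 2.59 and SERPINF1 -0.15.

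A minority of melanocyte-like cells of the orange male, 108 in cluster 21, clustered with those of the nonorange male and held TYRP1 at 3306 CPM, against 681 CPM in cluster 20. Barcodes shared between the male libraries were argued against, as 0 of the 108 cells (0 to 3.36%) carried one called in the nonorange male. Nonorange cells carried over were argued against as the whole cause, since the ARHGAP36 level would need 50.2% of the UMIs from them, and 4 of 8 genes kept out of the clustering, with at least 50 CPM and 2-fold more in nonorange cells of cluster 21 than in cluster 20, lay below that share of their nonorange level. These were DCT, PDE3A, PDE4D and PKIB, the last at 26.3% (23.5 to 29.5), whereas FOS, SERPINE2 and TYRP1 lay above it and PDE4B spanned it. By itself the share of cells with an ARHGAP36 UMI, 66.7% (56.9 to 75.4), did not decide between the 48.3% of a mixture with cells at 0 and the 86.4% of 1 common level, which also gave 93.4% for cluster 20 where 85.5% was observed, so a smaller carried share stays open and no biological explanation was tested.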

How the results depend on the processing

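No paired analysis was possible because each group holds 1 library. The gate without a rule on mast and Schwann markers and the clusters by number were chosen after seeing the data. Apart from named genes, 456 values stayed within their intervals, 46 moved beyond them and 6 reversed. Of named genes, 266 stayed, 76 moved and 2 reversed. Reversed was used only where the main interval excluded 0 and the sign changed. Other changes of sign, such as that of the pigment median under the gate, are counted as moved, or as stayed where they lay inside the interval. Clusters by number moved 16 of the 23 named genes and no list median, and Leiden resolutions of 0.5 and 2.0 moved nothing. The cause was not tested except where the construction shows it. Depth limits the shares of cells with a UMI, and low sums such as that of LUM.

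The planned gate on 3 of 8 markers kept 7.83% of the nonorange, 1.41% of the orange and 14.4% of the female cells, since it drops cells with any mast or Schwann marker, FABP7 and S100B included. Under it ARHGAP36 had a log2 ratio of at least 4.86, a bound set by the floor of 3 counts over fewer cells, and thinned shares of 3.45% in the orange male and 7.04% in the female. Medians between the males were -1.98 for pigment genes, -0.97 for regulators, -0.38 for pheomelanin (reversed), 0.49 for G2/M (reversed), 1.17 for stress (reversed), -0.19 for lysosome, 0.63 for MAPK, -2.77 for neural crest, 0.38 for cholesterol, 2.89 for keratin (reversed), -1.70 for collagen and -0.23 for housekeeping genes. FXYD6 (0.35) and NCKAP5 (1.27) reversed, the CREB list had -0.71 in the female split, and the female's positions were 0.0669 and 0.0305. Without the rule on mast and Schwann markers the gate kept 27.0%, 24.7% and 40.6% of the cells, with -0.020 for stress, 0.29 for keratin (reversed), positions of 0.630 and 0.373 and an ARHGAP36 share of 46.0% in the orange male.

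Melanocyte-like shares were 19.3%, 15.5% and 36.2% with no cell filter, 20.4% in the orange male with 1000 genes and 10% mitochondrial UMIs, and 20.4% and 19.5% in the nonorange and orange male with clusters per library. Clusters per library also gave -0.45 for S phase, -2.89 for G2/M and a position of 0.177 for lower genes, which was 0.214 with doublets left in. Positions for higher and lower genes were 0.509 and 0.376 with TMM, 0.502 and 0.384 with DESeq2 size factors, and 0.473 and 0.392 with totals without mitochondrial, ribosomal and globin genes. Thinned cells gave at least 7.96 for ARHGAP36, as the floor of 3 counts stands over a smaller total, and 0.0085 for keratin (reversed). Shares of cells with ARHGAP36 were 35.2% and 15.2% in the orange male and the female at 2000 UMIs per cell, 69.1% in the orange male at 8000 UMIs per cell, and 23.8% and 9.50% with 2 UMIs required.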

Other observations

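UMIs of KIT, the target of the enrichment, were also found outside melanocyte-like cells. For comparison, KIT stood at 1.01 and 0.863 CPM in cluster 2 of the nonorange and orange male and 0.991 CPM in cluster 0 of the female. It stood at 24.4, 2.40 and 3.21 CPM in suprabasal keratinocyte-like cells and 68.8 (16 UMIs), 15.0 and 16.2 CPM in fibroblast-like cells of the nonorange male, the orange male and the female. Background from free RNA is not excluded for the lowest of these levels. Cluster 18, with the taste and tuft cell genes GNAT3 and GNG13 and the cytokine gene TNFSF11 among its leading genes, held 215 cells of the nonorange male, 258 of the orange male and 10 of the female. KIT stood there at 68.9 CPM (60.5 to 78.2) and 70.1 CPM (62.8 to 78.0) in the males. Medians were 14600 and 15608 UMIs per cell in cluster 18 of the nonorange and orange male and 16046 and 16806 in cluster 2. Free RNA would reach cells of similar depth alike, so the level in cluster 2 argues against it as the whole source in cluster 18 of the males. Other sources were not tested. Cluster 11, with the tight junction gene CLDN3 and the protease gene MMP7 among its leading genes, had KIT at 121, 84.8 and 33.2 CPM in the nonorange male, the orange male and the female. ARHGAP36 had 0 UMIs in cluster 18 of the orange male, among 4781684 UMIs. That allows up to 0.627 CPM at the floor and 0.771 CPM by the exact interval. None of these clusters passed the rule for a name, and the 10 cells of the female in cluster 18 were too few to compare.

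Among X-chromosome neighbours of ARHGAP36, 3 of 18 measured genes were at least 1.5-fold higher in the orange male and 1 was lower, with a median log2 ratio of 0.22 (-0.09 to 0.51). The heparan sulphate genes HS6ST2 (2.51, 2.19 to 2.83) and GPC4 (1.69, 1.41 to 1.98) and FRMD7 (1.44, 0.47 to 2.46) were higher, and ELF4 had -0.77 on 6 and 16 UMIs. In the female split HS6ST2 had 1.48 (1.17 to 1.78) and GPC4 1.30 (0.84 to 1.75), and GPC3, also a neighbour, had 0.12 (-0.44 to 0.66). In the keratinocyte cluster the list had a median of -0.07 over 16 members, and under the gate on single-cell markers -0.072 over 17.

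G2/M genes were lower in cells with an ARHGAP36 UMI in both libraries that express it, with 12 of 14 members in the female and 11 of 14 in the orange male. CCNB2 had -1.57 (-2.52 to -0.75) in the female and -1.88 (-3.67 to -0.38) in the orange male. The orange male carries a single allele, so the split there does not compare alleles. S phase genes had medians of -0.52 and -0.49 in the female and the orange male.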
